A study of Homo sapiens with 6 samples.

How the data were processed

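Gene expression was measured in huh28 cells, an intrahepatic cholangiocarcinoma cell line, after 24 h in DMEM (Dulbecco's modified Eagle medium) alone or in DMEM with 500 nM microcystin-LR (MC-LR), per the labels. Each of the 6 arrays, 3 per group, was an Affymetrix Human Genome U133 Plus 2.0 array hybridised with biotin-labelled cRNA made from total RNA. The deposited values are log2 signals made by the authors with MAS5 and the affy package, per the submitters' processing notes; their versions are not given in the sources used here. MAS5 combines the probes of a probe set into 1 signal and scales each array to a common trimmed mean. The log base and the scaling were settled from the values: 2 raised to the deposited value had the same 2% trimmed mean, 500, on each of the 6 arrays. Detection calls, which say whether a signal lies above background, were not used here, so level stands in for detection.

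The table held 54675 probe sets, of which 62 were control probe sets and were kept out of the tests. Of the other 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none listed. Symbols were updated by gene ID for 41037 of the 41091, and 54 kept the platform's symbol. A probe set with several symbols was not assigned to a gene. No pseudocount and no further normalization between arrays were applied. Probe sets were tested when their mean log2 signal over the 6 arrays was at or above the median of all means, 7.81, which kept 27307. A gene was represented by its brightest probe set with 1 symbol, which gave 13586 genes.

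MC-LR arrays were compared with DMEM control arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had no covariates and 4 residual degrees of freedom. Every p-value below that is not called exact comes from limma or from its camera and fry tests. For 32 gene lists, camera compared the shift of the members with that of the other genes, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry, which asks whether members move one way on balance without comparing them with other genes, were run beside it. Members were counted over all genes tested and adjusted over the list alone. Array controls and the mean of each list were compared with a two-sided exact permutation test, whose smallest p for 3 arrays against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.

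The gene lists, the filter, the tests and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction that passed the threshold. From each list it took up to 4 passing members, or, where none passed over all genes, at most the 2 with the smallest p, as values only. It added the microcystin targets PPP1CA, PPP1CB, PPP1CC, PPP2CA and PPP2CB and the carriers SLCO1B1 and SLCO1B3. Alternatives fixed at the same time were quantile normalization, subtraction of array medians, log2 of the signal plus 16, no filter, only the upper 25% of probe sets, no intensity trend, the replicate number as a block, the mean of a gene's probe sets, an estimated correlation, and leaving out each array in turn, with each gene's brightest probe set chosen anew from the arrays left. Filters that kept only the top 10% or top 5% of probe sets, the metallothionein list without SLC30A1, and camera with its correlation and its degrees of freedom changed 1 at a time were added after the data had been seen. So were runs that left out each array with every gene's probe set held, which the numbers of alternatives given with ranges leave out.

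The fit was tested on simulated data: 10 simulations with 27307 probe sets tested, each with 200 changed probe sets. Values were drawn around the real means with limma's moderated spreads, which are pulled toward the intensity trend. They thus suit the fit under test better than the raw spreads would. Estimated changes followed the simulated ones with a slope of 0.998, and 20 unchanged probe sets were called over all simulations. Among the top 5% of probe sets by level, 32.4% of simulated log2 changes of 1 and 90% of those of 2 were called. In the rest of the upper 25%, 0.369% of log2 changes of 1 and 28.7% of those of 2 were called. Between the median and the upper 25%, 0 of 328 log2 changes of 1 and 3.69% of those of 2 were called. A shift of 0.5 given to 1 gene list was called by camera in 10 of 10 simulations, where genes varied independently.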

Results

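The series compared gene expression in huh28 cells, an intrahepatic cholangiocarcinoma line, with and without 24 h of microcystin-LR. Microcystin-LR is a cyanobacterial peptide toxin that inhibits the serine/threonine phosphatases PP1 and PP2A and enters hepatocytes through organic anion carriers. The 3 arrays of cells kept in DMEM alone were compared with the 3 arrays of cells given 500 nM MC-LR. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. No 2 arrays held identical values. Levels are deposited log2 signals, which were not remade here from probe-level data, so an unusual step in making them was not tested for. They are given as mean ± SD with n = 3 per group unless stated, and differences are MC-LR minus DMEM control.

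Levels of different probe sets are not comparable as amounts of transcript, and are given as signals only. The elongation factor EEF1A1 had a mean level of 19.75 over the 6 arrays, the initiation factor EIF1 19.39, the ribosomal protein RPLP1 19.26, the respiratory chain subunit COX6A1 19.10 and the tubulin TUBA1C 19.04. The intermediate filament vimentin (VIM) had a mean level of 17.37, and the keratins KRT7 and KRT18 of biliary epithelium had 11.29 and 10.27. KRT19 (5.81) and the epithelial adhesion gene EPCAM (7.63) lay below the filter. The glycolytic genes LDHA and PKM had mean levels of 8.48 and 8.38, while ENO1 had 9.57, TPI1 13.48 and GAPDH 15.56. Replicate spread depended strongly on level. The median SD within groups was 0.995 over all probe sets and 0.254 over the top 5%, and correlations between arrays of 1 group, taken across probe sets, which are not independent replicates, ranged from 0.665 to 0.701 over all probe sets and from 0.952 to 0.968 over the top 5%.

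**Figure D1:**
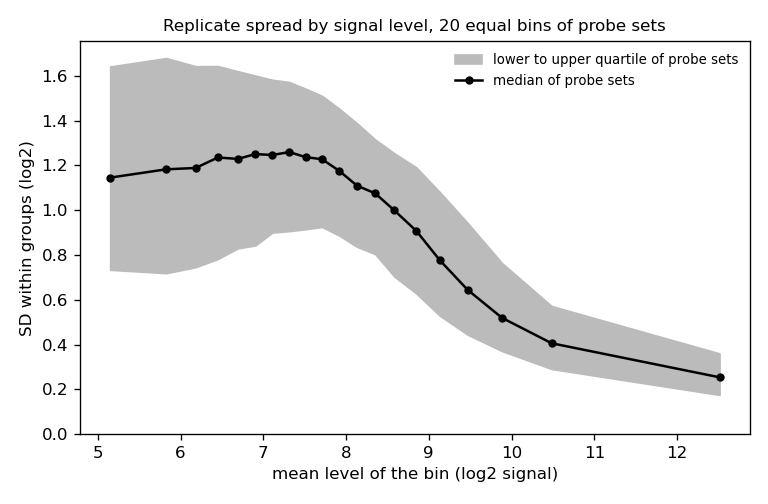
SD within groups (log2, y axis) against mean level (log2 signal, x axis) for 20 bins of equal size over all probe sets; points are medians of the probe sets in a bin and the band runs from their lower to their upper quartile. The median SD was 1.26 at a mean level of 7.31 and 0.254 at a mean level of 12.51.

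The targets and carriers of the toxin were measured first. PPP2CA, a catalytic subunit of PP2A, had a level of 16.29 ± 0.11 (SD, n = 3) in DMEM control and 16.09 ± 0.12 in MC-LR, a difference of -0.20 (SE 0.13). PPP1CA, a catalytic subunit of PP1, had 15.10 ± 0.16 and 15.10 ± 0.23. The differences were -0.29 (SE 0.15) for PPP1CC, 0.28 (SE 0.41) for PPP1CB and 0.17 (SE 0.42) for PPP2CB. SLCO1B1, a hepatic uptake carrier of the toxin, had 8.39 ± 0.94 and 8.43 ± 1.12. None of these 6 passed the test (lowest adjusted p 0.903). Both other probe sets of PPP1CB that passed the filter had the opposite sign, as did the other one of PPP5C and 1 of the others of PPP6R2. SLCO1B3 lay below the filter and was not tested, with levels of 7.07 ± 0.60 and 8.31 ± 0.21. Over the 31 tested PP1 and PP2A family phosphatases, 15 members were higher and 16 lower, with a median of -0.0040, a mean of 0.092, a downward direction in camera and 0 members past the test over all genes or adjusted over the list alone. The smallest p-values belonged to PPP5C (-0.77, SE 0.25) and PPP6R2 (1.44, SE 0.57).

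The listed metallothioneins, small metal-binding proteins induced by zinc, other metals and oxidative stress, were higher in the MC-LR arrays, as a list that also held the zinc exporter SLC30A1. All 7 tested members of the 8 listed, 6 metallothioneins and SLC30A1 (0.77), had a positive difference, with a median of 0.64, and the mean level of the list was 13.40 ± 0.56 in DMEM control and 14.10 ± 0.09 in MC-LR (SD, n = 3). MT1F had 16.04 ± 0.35 and 17.11 ± 0.32, a difference of 1.06 (SE 0.20). MT2A had 14.97 ± 1.06 and 16.30 ± 0.27, a difference of 1.33 (SE 0.38). The list was the only 1 of 32 called by camera with the preset correlation (adjusted p = 1.17e-05), and with the mean of each gene's probe sets the median was 0.33 (adjusted p = 0.0235; 1.60e-12 to 0.744 over 17 alternatives). The call was lost with the correlation estimated from the data (adjusted p = 0.744 with an estimated correlation), fry gave p = 0.1002 before adjustment, and an exact permutation test of the list mean gave p = 0.2. Without SLC30A1, a choice made after seeing the data, the median was 0.54 (camera p = 5.19e-07 before adjustment, and p = 0.0728 with an estimated correlation).

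Over all genes, 0 members of this list passed the test in limma, 3 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone, with adjusted p-values of 0.00104 for MT1F and 0.0165 for MT2A. MT1G, named because it is the remaining member of that count, had a difference of 0.64. The list means of the single arrays were 13.01, 13.15 and 14.04 in DMEM control replicates 1, 2 and 3, and 14.03, 14.06 and 14.20 in the MC-LR replicates, so DMEM control replicate 3 lay within the MC-LR range. Metallothionein probe sets share much sequence, so single members are uncertain: of 10 probe sets past the filter for the 6 metallothioneins, 9 were higher and 1, a dimmer probe set of MT1G, was lower (-1.85). The other probe set of SLC30A1 past the filter had a difference of -0.61. Tested metallothionein genes outside the list, looked up after the data had been seen, had differences of 0.84 (MT1HL1), -0.62 (MT3) and -2.08 (MT4), with none past the test over all genes. MT2A no longer passed over its list alone, with differences of 0.94 to 1.33, without DMEM control replicate 1 (adjusted p = 0.0752), DMEM control replicate 2 (0.0918), MC-LR replicate 1 (0.0598), MC-LR replicate 3 (0.0657) or the intensity trend (0.212; 2.30e-06 to 0.212 over 16 alternatives), and MT1F without the trend (0.207; 5.54e-05 to 0.207).

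**Figure D2:**
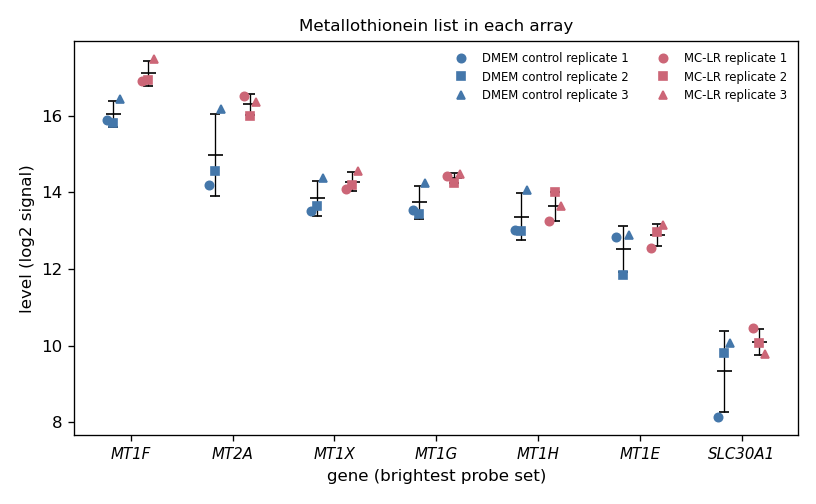
Level (log2 signal, y axis) of the 7 tested genes of the metallothionein list (x axis), with 1 symbol per array; blue stands for DMEM control, red for MC-LR, the symbol shape for the replicate number, and horizontal marks with bars for the mean ± SD of 3 arrays. MT2A lay at 14.18 and 14.54 in DMEM control replicates 1 and 2, at 16.18 in DMEM control replicate 3 and at 16.52, 16.003 and 16.37 in the MC-LR arrays.

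Poly-A control transcripts, which are spiked into RNA before labelling, were measured on the same arrays as the metallothioneins. The 3' minus 5' difference of the poly-A control phe was 1.22 ± 0.18 in DMEM control and 1.76 ± 0.10 in MC-LR, that of thr 2.07 ± 0.13 and 2.52 ± 0.23, and that of dap 0.99 ± 0.09 and 1.16 ± 0.05 (SD, n = 3). For each of these 3 the groups did not overlap (exact permutation p = 0.1, the smallest possible; adjusted p = 0.283 over 17 array measures). The labels give no labelling batch, and one that coincided with treatment would enter every MC-LR minus control difference. For lys the difference was 0.80 ± 0.37 and 0.89 ± 0.23 (exact permutation p = 0.7). The groups also did not overlap in the 3' minus middle (M) probe set differences of phe (0.93 ± 0.21 and 1.60 ± 0.31) and dap (0.08 ± 0.13 and 0.28 ± 0.07), though those of thr and lys did not separate them. Nor did they overlap in the array median, 8.106 ± 0.020 and 8.076 ± 0.015 (exact permutation p = 0.1 each). No normalization between arrays was applied in the main fit. The 3' probe sets of the cells' own ACTB and GAPDH were dimmer than the 5' ones on each array, by -5.34 ± 0.39 and -2.51 ± 0.34 over the 6 arrays, and these differences did not separate the groups (exact permutation p = 0.3 and 0.9).

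**Figure D3:**
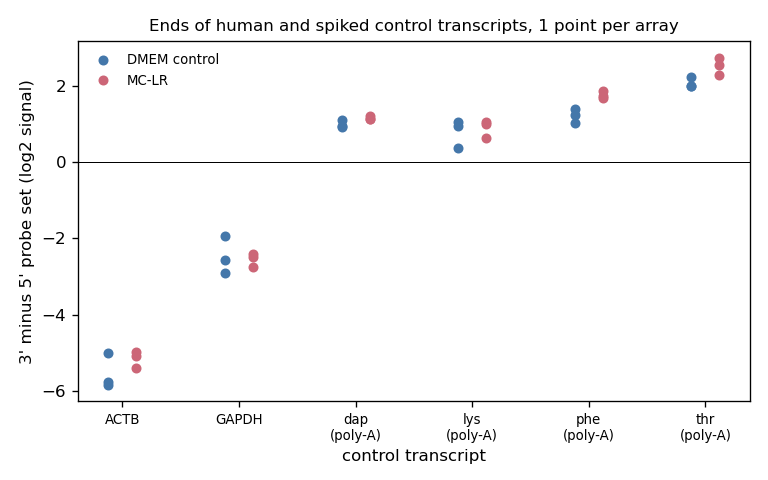
Difference of the 3' and 5' probe sets (log2 signal, y axis) of 2 human and 4 spiked poly-A control transcripts (x axis), with 1 point per array; blue stands for DMEM control and red for MC-LR. ACTB averaged -5.34 and GAPDH -2.51, while dap, lys, phe and thr averaged 1.08, 0.84, 1.49 and 2.30.

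Lists of stress responses and DNA replication came next by p. Targets of NRF2, the regulator of the oxidative stress response, had 17 of 21 members higher and a median of 0.29 (adjusted p = 0.0506; adjusted p = 0.852 with an estimated correlation); quantile normalization and subtraction of array medians brought it past the threshold (adjusted p = 0.0387 and 0.0382; 0.00734 to 0.852 over 17 alternatives). PRDX1, a peroxiredoxin that reduces hydrogen peroxide, had 16.27 ± 0.10 and 17.04 ± 0.25 (difference 0.77, SE 0.15) and was the list's 1 member that passed when adjusted over the list alone (adjusted p = 0.0044), though not over all genes (adjusted p = 0.903) and not without the intensity trend (0.332 over the list; 0.00200 to 0.332 over 16 alternatives). The median of the list was 0.061 without DMEM control replicate 2 (adjusted p = 0.561) and 0.16 without MC-LR replicate 1 (adjusted p = 0.265), and without DMEM control replicate 3 it was 0.41, or 0.45 with each gene's probe set held. The cystine carrier SLC7A11 had 9.68 ± 0.14 and 10.72 ± 0.23. Targets of ATF4, which responds to amino acid shortage and endoplasmic reticulum stress, had 17 of 25 members higher and a median of 0.20 (adjusted p = 0.123 in limma's camera, and 0.254 in fry), which was 0.31 without DMEM control replicate 3 and 0.32 in the upper 25% of probe sets. Their smallest p-values belonged to SLC7A11 and to the stress gene SESN2 (difference 1.20, SE 0.45), and 0 members passed over all genes or adjusted over the list alone. The mean level of the ATF4 list was 9.99 ± 0.09 in DMEM control and 10.20 ± 0.05 in MC-LR (exact permutation p = 0.1, the smallest possible). This test was run on the mean of each gene list, without adjustment over the lists. Only the ATF4 and DNA replication lists reached 0.1, where chance gives 10% of lists, so this value is no support for a shift of either. For the mean of the NRF2 list the exact permutation p was 0.3.

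DNA replication genes had 19 of 25 members lower and a median of -0.27 (adjusted p = 0.0666 in camera, and 0.744 with an estimated correlation). The mean level of the list was 9.93 ± 0.15 in DMEM control and 9.56 ± 0.13 in MC-LR (exact permutation p = 0.1, the smallest possible, unadjusted over the lists). The median was -0.15 without MC-LR replicate 1 (adjusted p = 0.240) and -0.43 without DMEM control replicate 3. CDC45, a subunit of the replicative helicase, had 10.74 ± 0.71 in DMEM control and 8.75 ± 1.04 in MC-LR (difference -2.00, SE 0.57), and RFC5, a clamp loader subunit, had 11.55 ± 0.22 and 10.81 ± 0.12. With 0 members past the test over all genes or adjusted over the list alone, these are values only, and the other probe set of RFC5 had the opposite sign. Mitosis genes split evenly, 12 higher and 12 lower, with a median of -0.06. CKS2 had a difference of -0.83 (SE 0.29) and BUB1 of 1.63 (SE 0.68). Without DMEM control replicate 3, the NRF2, ATF4, DNA replication and mitosis lists all passed camera (adjusted p = 0.0191, 0.0305, 0.0283 and 0.0308). Over all alternatives their adjusted p-values reached 0.852, 0.744, 0.744 and 0.965. Over the top 5% of probe sets, that control had a mean correlation of 0.963 with the MC-LR arrays, against 0.953 for DMEM control replicates 1 and 2. Leaving it out thus tends to widen the group differences, so these calls are no separate support for a shift.

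The transporter and endothelial marker lists each held 1 member that passed when adjusted over its list alone, and 0 that passed over all genes. The drug efflux pump ABCG2 had 10.11 ± 0.21 in DMEM control and 7.27 ± 0.88 in MC-LR (difference -2.84, SE 0.70; adjusted p = 0.0145 over the list, 0.903 over all genes). The MC-LR mean lay below the filter level of 7.81 and is not shown to be above background, so the size of this difference is uncertain. Leaving out DMEM control replicate 1, 2 or 3 ended this call with differences of -2.74, -2.84 and -2.95 (adjusted p = 0.0536, 0.0726 and 0.0542; 0.00652 to 0.0726 over 13 alternatives). The 9 tested organic anion transporters had a median of 0.35, with 7 higher. It was 0.067, 0.050 and 0.14 without DMEM control replicate 1, DMEM control replicate 2 and MC-LR replicate 2, 0.063 without MC-LR replicate 3, where another probe set became brightest (0.31 with probe sets held), 0.18 with no filter and 0.044 with the mean of a gene's probe sets. The bile salt carrier SLC10A1 had a difference of 2.02 (SE 0.72). Among endothelial markers, VWF had 10.69 ± 0.72 and 8.84 ± 0.28 (difference -1.85, SE 0.47, adjusted p = 0.0133 over the list, and 0.0127 to 0.304 over 13 alternatives). The call was lost without DMEM control replicate 2, where the difference was -1.44 (adjusted p = 0.139). It was also lost with the mean of its probe sets, where the difference was -1.16 (adjusted p = 0.304). TEK had a difference of -1.20 (SE 0.83), and the median over 7 endothelial markers was -0.0062, with a mean of -0.43.

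Markers of cell types that the line should not hold were measured too, with no detection calls to tell signal from background. Each marker was read by its brightest probe set but ranked among all single probe sets, which tends to raise the percentiles. The median level of 22 measured hepatocyte markers was 8.15, at the 57.9th percentile of all probe sets, with FGA at 9.61, and 13 passed the filter, while albumin (ALB, 7.79) did not. Fibroblast markers had a median level of 9.42 (81.8th percentile), with FBLN1 brightest at 12.68 and 14 of 14 past the filter. Leukocyte markers had 8.90 (73.5th), with CD79A brightest at 11.38 and 11 of 15 past the filter, but not PTPRC, CD14, TYROBP or CORO1A. Endothelial markers had 8.08 (56.4th), with PECAM1 brightest at 11.16 and 7 of 12 past the filter. Over the tested members, the median differences were -0.16 for hepatocyte, -0.26 for fibroblast and 0.13 for leukocyte markers. None of these 3 lists was called or had a member past the test over all genes or adjusted over the list alone, including TTR (1.22, SE 0.65), APOA2 (-1.71, SE 0.84), DCN (1.59, SE 0.65), COL3A1 (-1.23, SE 0.59), LCP1 (1.27, SE 0.66) and CSF1R (-1.38, SE 0.73).

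Stress and death genes outside these lists showed no shift that passed the test. Genes of the unfolded protein response had a median of 0.17, with the chaperone HSPA5 at 13.72 ± 0.50 and 14.39 ± 0.28 and HYOU1 at a difference of 0.61 (SE 0.30). Cytosolic heat shock genes had a median of -0.10, with STIP1 at 0.76 (SE 0.55) and CRYAB at -0.36 (SE 0.26). Targets of p53 had a median of 0.11, with SESN2 as above and TRIAP1 at -1.29 (SE 0.60), and apoptosis regulators had a median of 0.04, with DIABLO at -1.44 (SE 0.60) and BID at -1.26 (SE 0.71). Glutathione genes had a median of -0.07, with GPX1 at -1.13 (SE 0.37) and GCLC at -0.91 (SE 0.55). Targets of xenobiotic receptors had a median of 0.0089, with UGT1A1 at 2.22 (SE 0.84) and UGT1A6 at -1.57 (SE 0.88). Autophagy and lysosome genes had a median of -0.08, with CTSL at -2.00 (SE 0.83) and GABARAPL2 at -1.60 (SE 0.69).

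Signalling and structural gene lists had medians between -0.17 and 0.19, and none was called. Inflammatory genes had a median of 0.19 and a mean of -0.06, with the chemokine CXCL1 at 9.42 ± 0.50 and 6.60 ± 1.17 and the cytokine IL1B at a difference of -0.78 (SE 0.28). Interferon-stimulated genes had a median of -0.16, with IFIT2 at -1.58 (SE 0.87) and OAS3 at 0.80 (SE 0.46). Immediate early genes had a median of 0.0062, with the ERK phosphatases DUSP6 at 1.06 (SE 0.45) and DUSP1 at -0.42 (SE 0.24). Targets of YAP and TGF-beta had a median of 0.16, with PMEPA1 at 1.57 (SE 0.94) and CCN1 at -0.56 (SE 0.37), and Wnt targets -0.17, with DKK1 at 1.78 (SE 0.95) and AXIN2 at -1.14 (SE 0.63). Actin and focal adhesion genes had a median of -0.08, with the integrin ITGA3 at -2.02 (SE 0.61) and the myosin MYH9 at 1.95 (SE 0.71). Mesenchymal genes had a median of 0.03, with VIM at -0.58 (SE 0.20) and TIMP2 at 0.34 (SE 0.15), and epithelial genes 0.04, with CTNNB1 at -0.30 (SE 0.17) and PKP3 at -0.42 (SE 0.26).

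No metabolic or ribosomal list was called. Cholesterol synthesis genes had a median of -0.20, with TM7SF2 at 1.30 (SE 0.51) and ACAT2 at -0.76 (SE 0.38), and fatty acid genes -0.23, with HADHA at -0.60 (SE 0.37) and ACADVL at 1.08 (SE 0.74). Glycolysis and hypoxia genes had a median of 0.11, with PGAM1 at -1.81 (SE 0.77) and VEGFA at 0.38 (SE 0.17), and respiratory chain genes 0.06, with ATP5PO at -2.18 (SE 0.73) and NDUFB3 at 1.77 (SE 0.75). Ribosomal protein genes had a median of 0.02, with RPS23 at 0.69 (SE 0.22) and RPS6 at -0.47 (SE 0.19), and ribosome biogenesis genes 0.15, with WDR12 at 0.89 (SE 0.27) and RRP9 at 1.55 (SE 0.52). Beyond the 4 lists with the smallest p-values, the other 28 lists had adjusted p-values of 0.779 or more. The same limit as for ABCG2, a group mean below the filter level, holds for CXCL1, SLC10A1, UGT1A1, UGT1A6, CTSL, PGAM1, DKK1, IFIT2, PMEPA1 and TEK. For GCLC, BID, IL1B, VIM, TIMP2, CCN1, AXIN2, RPS6 and DCN at least 1 other probe set past the filter had the opposite sign. None of the 32 lists was called with an estimated correlation or by fry, where ATF4 targets and fibroblast markers had the smallest adjusted p (0.254). The camera direction opposed the median for the inflammatory, epithelial, mesenchymal, immediate early and apoptosis lists, and the apoptosis mean was -0.07.

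**Figure D4:**
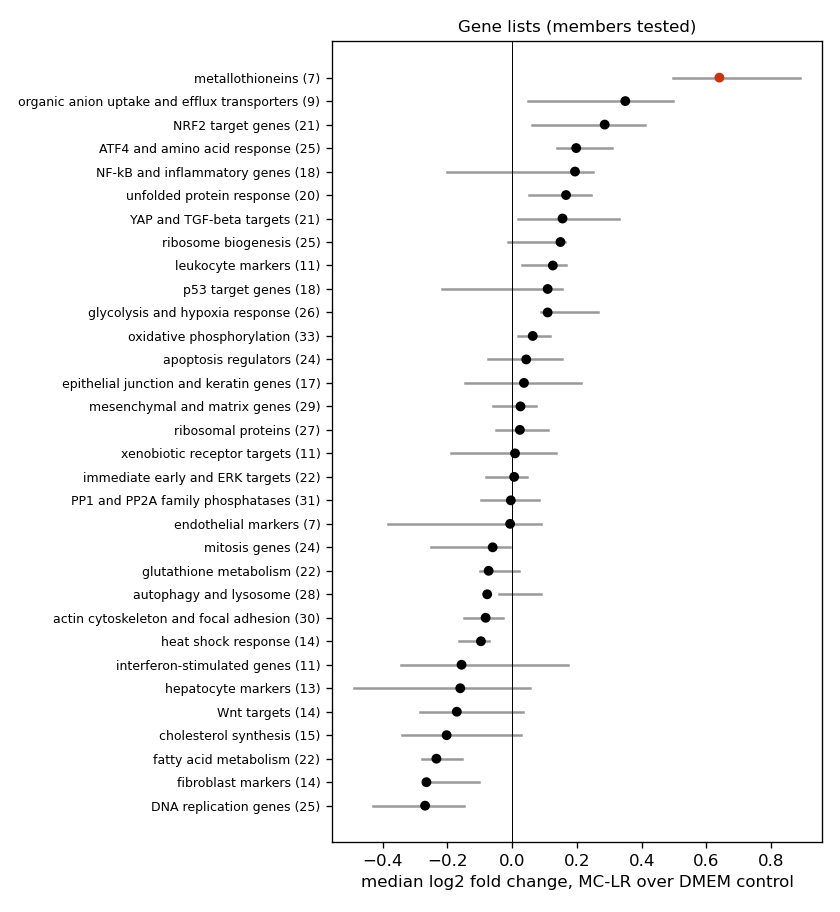
Median log2 fold change of MC-LR over DMEM control (x axis) for the 32 gene lists (y axis), with the number of tested members in parentheses; points are the medians over 6 arrays, red where camera with the preset correlation called the list, and grey bars run from the lowest to the highest median when 1 array is left out and each gene's brightest probe set is chosen anew, which need not hold the point. The metallothionein median was 0.64, with a range of 0.50 to 0.89.

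Across the transcriptome, limma called 0 of 27307 probe sets (smallest adjusted p 0.371) and 0 of 13586 genes (smallest adjusted p 0.883), and therefore 0 genes at least 2-fold. At an unadjusted p under 0.05 there were 745 genes, 369 higher and 376 lower, or 5.48%, where chance gives 5%, or 679.3 genes. The groups did not overlap for 1487 genes, 10.9%, where chance gives 10%. Without DMEM control replicate 3, 2 genes passed: MT2A (1.93, adjusted p = 0.00896) and EIF5 (-1.19, adjusted p = 0.028). Leaving it out also brought HSPA5, CRYAB, CKS2, VIM, ACAT2 and WDR12 past the threshold when adjusted over the list alone (adjusted p = 0.00556, 0.00314, 0.000509, 0.00140, 0.0103 and 0.000298). Among the other arrays, leaving out MC-LR replicate 1 did so for CDC45 (0.0468), MC-LR replicate 3 for ATP5PO (0.0465) and GABARAPL2 (0.00197), and DMEM control replicate 1 for DCN (0.0303). The gains without DMEM control replicate 3 are no separate support for a difference, as that control was more like the MC-LR arrays than the other controls were. With each gene's probe set held, leaving out 1 array moved the difference of 33 of 72 named genes by over 1.5 times. The median SE of a difference was 0.61 over all genes tested and 0.23 over those in the top 5% of signals, so changes of 2-fold in most genes were not detectable with 3 arrays per group.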

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

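The filters that kept only the top 10% or top 5% of probe sets were chosen after seeing the data, as were the count of members past the threshold over their list alone, the changes to camera's degrees of freedom and the runs that held each gene's probe set, while the other alternatives were fixed beforehand. Limma called 0 genes, and 0 of them at least 2-fold, under each alternative that kept all 6 arrays, with 464 genes at an unadjusted p under 0.05 in the upper 25% of probe sets, 238 in the top 10% and 147 in the top 5%, where fewer genes were tested, and 646 to 1074 elsewhere. Leaving out 1 array gave 0 to 3 probe sets, 0 to 2 genes, 0 to 2 genes at least 2-fold and 1 to 5 gene lists. The single probe set arose without DMEM control replicate 1, and the highest counts without DMEM control replicate 3, which also took the members past the threshold over their list alone from 6 to 17, or to 16 with probe sets held. Without the intensity trend these members were 2. The rise without DMEM control replicate 3 goes with the likeness of that control to the MC-LR arrays and is no separate support for a difference. With the replicate block there were 0 genes (lowest adjusted p 0.208), 723 at an unadjusted p under 0.05 and 1 list, and CDC45 passed over its list alone (adjusted p = 0.0492; 0.0468 to 0.402 over 14 alternatives). Arrays that shared a number did not deviate together (correlations of deviations across probe sets 0.00082, -0.012 and -0.0059), so the numbers were not taken to pair the arrays.

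The metallothionein median kept its sign under the 17 alternatives, from 0.33 with the mean of a gene's probe sets to 0.89 without DMEM control replicate 3, and was called in 16. The estimated correlation left 0 lists called, but this option also tests on 4 degrees of freedom in place of 13584. An estimated correlation on 13584 degrees of freedom and the preset one on 4 each called 0 lists too (lowest adjusted p 0.149 and 0.225), with p = 0.0139 and 0.00704 before adjustment for the metallothioneins. There were 2 lists called with quantile normalization and with array medians subtracted (NRF2 targets added, adjusted p = 0.0387 and 0.0382), with no filter and with the mean of a gene's probe sets (DNA replication genes added, 0.0426 and 0.0235), in the upper 25% (ATF4 targets added, 0.0227) and in the top 10% and top 5% (NRF2 targets added, 0.00734 and 0.0314). Without MC-LR replicate 2, NRF2 targets also passed (0.0244). Over its list alone, SLC10A1 passed with the mean of a gene's probe sets (0.0439) and SLC7A11 in the top 10% among NRF2 targets (0.0397). In the upper 25%, the top 10% and the top 5%, 29, 23 and 16 lists kept enough members for a test. The cause of these added calls was not tested.

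Signs turned for 30 results under some alternative, and in 0 of these comparisons was the value past the threshold on either side. Of 499 comparisons of uncalled list medians, those with probe sets held aside, 67 changed sign. With the mean of a gene's probe sets, medians became -0.0062 for inflammatory, 0.16 for fibroblast, -0.081 for glycolysis, 0.056 for interferon-stimulated, 0.052 for mitosis, -0.00900 for ribosomal protein and -0.023 for unfolded protein response genes, and PPP1CB came to -0.096 and RPS6 to 0.39. With no filter they were -0.063 for inflammatory, -0.093 for epithelial and 0.063 for glutathione genes. With array medians subtracted, PPP1CA, the middle gene of the phosphatases, and their median came to 0.026 and endothelial markers to 0.024. Log2 of signal plus 16 gave 0.036 for the phosphatases, and quantile normalization gave -0.00103 for immediate early genes. In the upper 25% the medians were -0.079 for YAP and TGF-beta targets, 0.047 for autophagy, -0.093 for epithelial, 0.18 for fatty acid, -0.073 for immediate early and -0.18 for p53 target genes. In the top 10% they were 0.057 for actin, 0.17 for autophagy, -0.093 for epithelial, 0.063 for glutathione, -0.15 for immediate early and -0.00389 for unfolded protein response genes. In the top 5% they were 0.066 for actin, 0.22 for autophagy, -0.093 for epithelial, -0.16 for mesenchymal and -0.037 for unfolded protein response genes. The cause was not tested.

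Leaving out 1 array also made another probe set the brightest of 273 to 328 genes. With each gene's probe set held, the calls of genes and lists were as many for each array left out, with 624 to 841 genes at an unadjusted p under 0.05. Over the runs with probe sets chosen anew and held, medians crossed 0 as follows: phosphatases -0.095 to 0.084, glutathione -0.099 to 0.020, xenobiotic -0.19 to 0.13, p53 -0.22 to 0.15, apoptosis -0.075 to 0.15, immediate early -0.080 to 0.046, inflammatory -0.20 to 0.25, interferon -0.34 to 0.17, mesenchymal -0.083 to 0.075, epithelial -0.15 to 0.21, Wnt -0.28 to 0.033, cholesterol -0.35 to 0.027, ribosomal protein -0.048 to 0.11, ribosome biogenesis -0.026 to 0.16, autophagy -0.042 to 0.089, hepatocyte -0.49 to 0.056, YAP and TGF-beta targets -0.0038 to 0.33 and endothelial -0.38 to 0.088. Others kept their sign: actin -0.15 to -0.028, mitosis -0.25 to -0.0079, fatty acid -0.28 to -0.16, fibroblast -0.28 to -0.075, heat shock -0.17 to -0.072, glycolysis 0.090 to 0.26, leukocyte 0.031 to 0.17, respiratory chain 0.019 to 0.12 and unfolded protein response 0.052 to 0.24. With the probe set held, 33 of 72 named genes moved by over 1.5 times. Signs turned for PPP1CA (-0.11 to 0.12), PPP2CB (-0.075 to 0.45) and SLCO1B1 (-0.54 to 0.57), and values moved by over 2 times for ACADVL (0.24 to 1.88), CRYAB (-0.75 to -0.099), TTR (0.53 to 1.90), DCN (0.71 to 2.35), NDUFB3 (0.81 to 2.36) and DIABLO (-1.83 to -0.67). Another probe set gave AXIN2 0.45 without MC-LR replicate 3 (-1.65 to -0.87 held), GCLC -0.0069 without DMEM control replicate 1 (-1.28 to -0.61 held) and DCN 0.36 without MC-LR replicate 2.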

Other observations

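The tests of explanations and of splits below were chosen after the results they measure had been seen, and the genes of the first paragraph were picked by their small p-values. Not every gene with so small a p was named, and TRIO was left out. None of those genes passed the test over all genes. The proteasome subunit PSMB6 had 14.12 ± 0.28 in DMEM control and 15.22 ± 0.31 in MC-LR (SD, n = 3; difference 1.11, SE 0.19, adjusted p = 0.883), higher in 3 of 3 MC-LR arrays than in any control. The splicing factor PUF60 had 12.74 ± 0.17 and 11.83 ± 0.14, and the non-coding transcript STX17-DT 13.34 ± 0.10 and 12.47 ± 0.25. LAMP5 had 10.26 ± 0.04 and 7.47 ± 0.19, the latter below the filter level.

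Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05, so they cannot say whether chance is excluded. The real split gave 745 genes at an unadjusted p under 0.05 against at most 682 in another split, and 1 of the 10 reached that count. It gave 0 probe sets, 0 genes and 0 genes at least 2-fold against at most 1 of each in another split, so 10 of 10 were as large. It gave 1 gene list against at most 3, and 4 of 10 were as large. Those 4 were the splits that kept DMEM control replicates 1 and 2 in the same group, and the splits that parted them gave 0 lists. With MC-LR replicate 2 or 3 in the place of DMEM control replicate 3, 2 and 3 lists were called.

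The 3' ends of the human control transcripts were dim. Degraded RNA or a low yield of labelled RNA may be present. Labelling starts at the 3' end, so neither is by itself a ready account of 3' signals below the 5' ones. The ACTB 3' minus 5' difference, -5.34 ± 0.39 over 6 arrays, is the pattern itself and so no separate test of either. The 2 probe sets may also differ in response, which was not measured, so how much of this difference needs a cause is not known. Transcript 3' ends that match the human probes poorly stay open, as does an unusual step in making the deposited values, which was not tested. A list of 14 measured RNA-binding protein genes, whose ends are often conserved, lay 2.47 above a list of 32 abundant housekeeping genes (95% bootstrap interval -0.27 to 3.24), which decides nothing, as abundance and probe response differ between genes too, and an earlier form of these lists that held 21 more RNA-binding and 7 more housekeeping genes, whose levels had already been seen, had given 4.25 and was set aside as circular. RNA of a non-primate species may be one source, but the probe set for the primate Alu repeat lay at the 99.7th percentile, which related repeats could also give, and no biological explanation was tested.

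DMEM control replicate 3 lay nearer to the MC-LR arrays than to the other controls, with mean correlations of 0.963 and 0.953 over the top 5% of probe sets. Over the 27307 tested probe sets this was not particular to it. There DMEM control replicates 1 and 2 correlated at 0.667 with each other and 0.676 with the MC-LR arrays. The first principal component, the main axis of difference between arrays, there set DMEM control replicate 2 (-144) apart from the other 5 arrays (12.8 to 38.6). A labelling difference that puts DMEM control replicate 3 with the MC-LR arrays stays open, as it need not show in the ends of spiked controls. Its 3' minus 5' difference lay within the MC-LR range for only 1 of the 4 poly-A controls, lys, which did not separate the groups. For phe (1.03) and dap (0.93) it lay farther from that range than in either other control. This argues against a labelling difference that shows in those ends. For thr (2.22) it lay between the other controls (2.01 and 1.99) and the lowest MC-LR value (2.28). A wrong label may be a cause and stays open. For probe sets chosen without DMEM control replicate 3, its position between the other controls (0) and the MC-LR arrays (1) was 0.72. The other 5 arrays, held out in turn, lay at 0.589 to 0.680. The probe sets were chosen for a difference between the arrays left, which draws a held-out array away from 0 even where the groups do not differ. These positions therefore decide nothing about the label. A difference between cultures was not tested.

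For the shift of the metallothionein list, the small camera p depended on the preset correlation of 0.01. With the correlation estimated as 0.59 on the same 13584 degrees of freedom, p rose from 3.66e-07 to 0.0139. ATF4 targets (0.00701) and DNA replication genes (0.0134) then had smaller p-values in camera. On 4 degrees of freedom the p was 0.0697, where each of the 32 lists had a p above 0.05. Whether related probe sets that share signal and are counted as separate genes gave this correlation stays open, as genes regulated together correlate too. A labelling difference that moves all bright transcripts alike is argued against as the whole cause of this shift. Of 10000 random lists of equal size and level, 0 had a median as high as 0.64 (highest 0.43). Such lists hold unrelated genes, while this list was picked by its shift and its genes were correlated at 0.59. The count is therefore no measure of chance, and a labelling difference particular to this family stays open. A difference of DMEM control replicates 1 and 2 from the other arrays may be a cause and stays open: DMEM control replicate 3 had a list mean of 14.04 and reached the MC-LR range in 5 of 7 members, but not in MT1F (16.44 against 16.92 to 17.48) or MT1G (14.23 against 14.24 to 14.47). A labelling batch that coincided with treatment was not tested and stays open, as the 3' minus 5' differences of phe, thr and dap did not overlap between the groups (exact permutation p = 0.1, the smallest possible). An effect of MC-LR stays open too. Camera with the preset correlation called the list, and 3 members passed in limma when adjusted over the list alone. Camera with an estimated correlation, fry and the exact permutation test of the list mean did not call it.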
